A study of Cicer arietinum with 2 samples.

How the data were processed

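Total RNA was extracted with TRIzol from pooled flower and pooled leaf tissue and small RNA libraries were made by the Illumina protocol, per the labels' protocols. The series' design text names the Illumina GAII as the sequencer. The authors deposited, for each of the 2 libraries, a table of 2 columns without a header that holds each distinct sequence and its raw count of reads. The lengths in the tables run from 18 to 29 nt and the counts are whole numbers from 1 upward. The trimming tool, filters, aligner and genome build are not given in the sources used here. How adapters were removed matters for the values, since tags with adapter sequence remain in both tables.

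Groups were taken from the tissue given in the labels, with 1 library per tissue. Counts were scaled to reads per 1000000 reads (RPM) over all reads of a table, 13491628 in the library labelled flower and 25259578 in the library labelled leaf. A ratio is the flower-labelled over the leaf-labelled value, with an exact conditional binomial 95% interval. Shares have exact (Clopper-Pearson) binomial 95% intervals, and a count of 0 was taken to allow 3 counts. PCR copies are not independent molecules, so intervals cover counting error only. No test across libraries was made.

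Families, lists and reference sequences were written from general knowledge before the data were examined: 42 plant families in 9 lists and 10 control families, 65 reference sequences in all. A tag of 19 to 24 nt joined a family with at most 2 mismatches over the overlap and both ends within 2 nt of the reference, and went to the family with the fewest mismatches. The family names are those of the closest reference and not loci of chickpea. A family counted as higher in a library with at least 50 reads over both libraries, a ratio of at least 2 and an interval without 1. For each list the median log2 ratio, with 0.5 added to each count, was placed among 10000 random lists of tags of 20 to 22 nt and at least 50 reads, each drawn from the 100 tags nearest in abundance, outside the adapter and the listed tRNA and rRNA. The sharing of 24-nt sequences was computed after thinning to the smaller library, as planned. The planned range went up to 30 nt, and the tables end at 29 nt.

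The families named were fixed by rule before the data were examined: the 10 with the highest and the 10 with the lowest ratio among those with at least 50 reads, miR156/miR157, miR172, miR165/miR166, miR390, tasiARF and every phased siRNA trigger. Of tags of 20 to 22 nt in no family, the rule named the 5 most abundant per library and, with at least 500 reads, the 5 with the largest ratio in each direction.

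After the data were examined, 13 tRNA and rRNA sequences were written from general knowledge, without a check against a database, and 11 were kept, those of which the tags covered at least 90%. A tag joined such a class when it matched exactly. Adapter tags were those that held 14 nt in a row of the 26-nt 5′ adapter of the Illumina small RNA kit or its 3′ end with the following bases. Variants were tags that differed at 1 base from a tag at least 20 times more abundant. Rates by base used abundant tags with at least 1000 reads. Tags with a shifted 5′ end were paired when they matched exactly over their overlap of at least 15 nt. Tags at least 2-fold apart were set against 20 random splits of the reads.

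The procedures were tested on simulated data. Of 2090 simulated family members, 100% were recovered, and 1 of 200000 random sequences was assigned. Of 100 tags changed 3-fold, 97 were called, as were 100 of 100 changed 4-fold and 162 of 30804 unchanged tags. Intervals held the true ratio for 96.2% of 31004 tags. When the reads were split at random, the shared 24-nt sequences divided by the expected number gave 1.001, and 0.901 when 10% of the sequences were placed in 1 library only.

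Alternatives changed the scaling, the family definition, the minimum number of reads and the depth. Annotation classes, phased loci and every alternative that needs genome matches were planned and not run, since no genome sequence was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.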

Results

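Small RNA was sequenced from chickpea, Cicer arietinum, a cool-season grain legume, grown in a glasshouse at 25 °C by day and 21 °C by night without treatment. The labels name 1 library from pooled flower tissue and 1 library from pooled leaf tissue, made to identify microRNAs and phased small interfering RNAs. The library labelled flower held 13491628 reads of 18 to 29 nt in 2294606 distinct sequences, of which 81.9% were read once. The library labelled leaf held 25259578 reads in 3956819 distinct sequences, of which 80.7% were read once. With 1 library per tissue, no difference below has a replicate check and no p-value is given. The intervals are 95% intervals for counting error only, and a count of 0 allows up to 0.222 reads per 1000000 reads (RPM) in the library labelled flower and 0.119 in the library labelled leaf. As the values below show, the small RNA populations of the libraries were almost the same, so each is called by its label and not by a tissue.

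The first comparison was the length profile of each library. The 24-nt class, the usual length of the siRNAs that direct DNA methylation at plant repeats, was the most abundant length in both libraries when sequences read once were counted. It made up 19.2% of reads in the library labelled flower (19.2 to 19.3, exact binomial interval) and 19.8% in the library labelled leaf (19.8 to 19.8). The 21-nt class, which holds most plant microRNAs, made up 14.5% and 14.4%. The ratio of 24-nt to 21-nt reads was 1.33 in the library labelled flower (1.33 to 1.33) and 1.37 in the library labelled leaf (1.37 to 1.37). Over tags with 2 or more reads it was below 1, at 0.850 and 0.952. These counts kept adapter, tRNA and rRNA reads, which weigh more on the 21-nt class. Over all reads of the library labelled flower, leaving them out took 21-nt reads from 1954940 to 1111923. It took 24-nt reads from 2595160 to 2226642. For tags with 2 or more reads, the ratio without these classes was not computed. Among distinct sequences the 24-nt class was more dominant, at 55.9% and 55.6%, and the ratio was 7.01 and 7.07. Distinct 24-nt sequences began with adenine in 48.96% of cases in the library labelled flower and 48.54% in the library labelled leaf. Distinct 21-nt sequences began with uracil in 40.1% and 40.4%. These shares by first base leave out the adapter and the listed tRNA and rRNA.

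**Figure D1:**
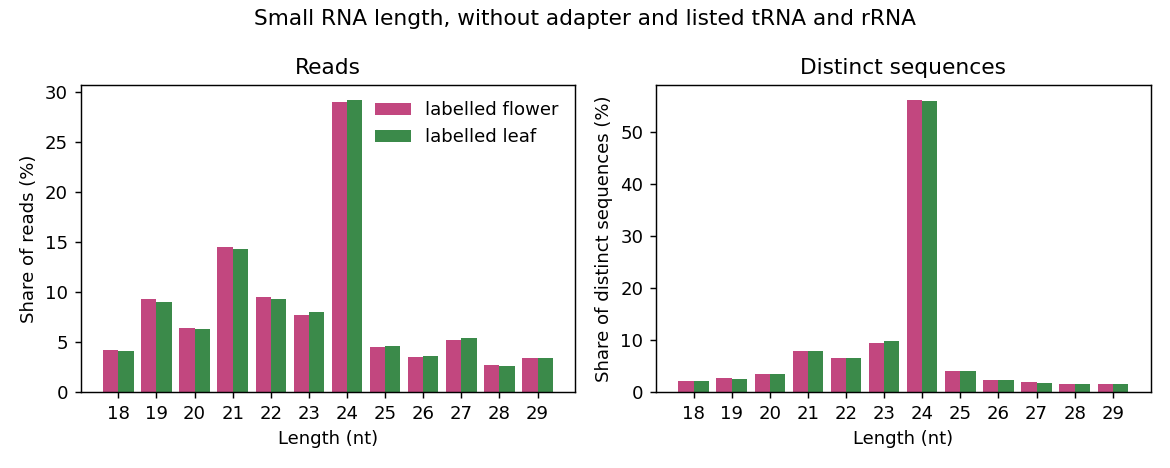
Share of reads (left) and of distinct sequences (right), in percent, at each length from 18 to 29 nt in the library labelled flower and the library labelled leaf, without adapter tags and the listed tRNA and rRNA fragments. The 24-nt class holds 28.99% and 29.23% of these reads and 56.3% and 56.0% of the distinct sequences.

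A large part of the reads came from other RNA classes and from the library adapter. Fragments of chloroplast-type tRNA made up 16.1% of reads in the library labelled flower and 14.99% in the library labelled leaf, a ratio of 1.07 (1.07 to 1.07). Fragments of nuclear tRNA made up 2.85% and 2.87%, and fragments of rRNA 6.16% and 5.99%. Tags with a stretch of the 5′ adapter made up 17.97% and 18.67%. Without these classes the ratio of 24-nt to 21-nt reads was 2.003 in the library labelled flower and 2.048 in the library labelled leaf.

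The second comparison was the abundance of conserved microRNA families. Of 42 plant families searched, 34 had at least 50 reads over both libraries, and these differed little between the libraries. Of the 34, 1 was at least 2-fold higher in the library labelled flower with an interval that left out 1, and 0 in the library labelled leaf. The ratio of RPM values, flower-labelled over leaf-labelled, lay between 0.8 and 1.25 in 30 families. Among the 21 families with at least 500 reads it ran from 0.927 for miR390 to 1.21 for miR408. The interval left out 1 in 11 of the 34 families, 8 with the higher value in the library labelled flower and 3 in the library labelled leaf. By counting error alone, 1.7 of the 34 families would have an interval without 1. With scaling to the median family the 8 and 3 became 3 and 7. Of the 26 named families with at least 50 reads, 8 had a ratio that crossed 1 under at least 1 alternative: miR162, miR167, miR172, miR390, miR393, miR398, miR858 and miR1509. The minimum of 50 reads was not applied again within an alternative for these ratios. The crossings of miR393, miR398 and miR858 rest on few reads. The most abundant sequence of miR393 had 18 and 29 reads, and that of miR858 had 10 and 18. Together the 42 plant families held 3.057% of reads in the library labelled flower and 3.001% in the library labelled leaf.

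Both families of the phase change and flowering list were among the most abundant. miR156/miR157, which targets SPL transcription factors and holds plants in the juvenile phase, stood at 9878 RPM in the library labelled flower and 9418 in the library labelled leaf. Its ratio was 1.05 (1.04 to 1.06). miR172, which targets APETALA2-like factors and promotes flowering, stood at 8271 and 8100 RPM, a ratio of 1.02 (1.01 to 1.03). With scaling to the median family, the ratio of miR172 was 0.983 and that of miR156/miR157 was 1.01. miR156/miR157 was read mostly as TGACAGAAGAGAGTGAGCAC and miR172 mostly as AGAATCTTGATGATGCTGCAT.

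Of the 8 measured families in the list that targets developmental transcription factors, 5 had a ratio above 1 and 3 below, against 2 and 6 with scaling to the median family. miR165/miR166, which targets the HD-ZIP III factors of leaf and vascular polarity, stood at 7443 and 7611 RPM, a ratio of 0.978 (0.971 to 0.985). With exact reference sequences only, or its most abundant sequence only, that ratio was 0.996, above this interval and nearer to 1. miR159, which targets MYB factors of the GAMYB type, had a ratio of 0.942 (0.901 to 0.985). The ratio of miR319, which targets TCP factors, was 1.12 (0.858 to 1.45). For miR858, which targets other MYB factors, 56 reads gave a ratio of 0.816 (0.433 to 1.48).

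Of the 5 measured families of the auxin list, 2 had a higher value in the library labelled flower and 3 in the library labelled leaf. miR160, which targets repressing auxin response factors, had a ratio of 1.13 (1.01 to 1.26). miR167, which targets activating auxin response factors, had a ratio of 0.982 (0.956 to 1.01). miR390, which starts production of the trans-acting siRNAs from TAS3, stood at 39.7 and 42.8 RPM, a ratio of 0.927 (0.835 to 1.03). The siRNA made from TAS3 itself, tasiARF, stood at 23.57 and 22.01 RPM, a ratio of 1.07 (0.930 to 1.23). miR393, which targets auxin receptors, had a ratio of 0.839 (0.507 to 1.35).

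The 5 measured families of the nutrient response list all had a higher value in the library labelled flower, but with exact reference sequences only the ratio of miR398 was 0.936. That value rests on few reads, since the most abundant miR398 sequence, 14 and 21 of its 31 and 46 reads, is not an exact reference sequence. miR408, which targets copper proteins, had a ratio of 1.21 (1.05 to 1.39). The ratio was 1.26 for miR398 (0.773 to 2.03), which targets copper superoxide dismutases, and 1.09 for miR397 (0.863 to 1.37), which targets laccases. For miR2111, which is induced by low phosphate, it was 1.27 (0.915 to 1.75). The median log2 ratio of the list was 0.28, at percentile 98.5 among 10000 random lists of tags of like abundance. That percentile describes these libraries and is not a test of the tissues.

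Families that set off phased siRNA production were led by miR482/miR2118, which targets disease resistance genes of the NB-LRR type. It stood at 160.8 and 150.2 RPM, a ratio of 1.07 (1.02 to 1.13), and 93.6% of its reads were 22 nt long. miR5213 stood at 93.9 and 98.8 RPM, a ratio of 0.9504 (0.888 to 1.02). The ratio was 1.07 for miR1507 (0.887 to 1.30) and 0.996 for miR1509 (0.587 to 1.65). miR828, which targets MYB genes, had 0 reads in the library labelled flower and 10 in the library labelled leaf. No read was assigned to miR1510 or miR1515. The median log2 ratio of the 4 measured families was 0.05, at percentile 72.1.

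In the small RNA pathway list, miR168, which targets ARGONAUTE1, had a ratio of 0.949 (0.920 to 0.980). miR162, which targets DICER-LIKE1, had a ratio of 1.10 (0.883 to 1.37), and miR403, which targets ARGONAUTE2, had 15 and 46 reads and a ratio of 0.611 (0.317 to 1.11). Among legume families, miR4414 was the family past 2-fold, with 27 and 25 reads and a ratio of 2.02 (1.13 to 3.63). Its ratio was 1.95 with scaling to the median family, 2.31 with its most abundant sequence only and 2.66 with tags of at least 5 reads. At equal depth it had 27 and 15 reads, less than 2-fold apart. miR5232 had a ratio of 1.15 (1.01 to 1.31). In the list of other conserved families, the ratio of miR394 was 0.943 (0.824 to 1.08) and that of miR530 1.17 (0.856 to 1.60). The pollen-associated list had no family with 50 reads: miR845 had 6 reads in the library labelled flower and 0 in the library labelled leaf, and miR2275 had none.

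The remaining list medians were small. The median log2 ratio was 0.05 for phase change and flowering (percentile 60.8), 0.04 for developmental transcription factors (64.2) and -0.03 for auxin (19.1). It was 0.08 for other conserved families (63.3), -0.07 for the small RNA pathway (19.96) and 0.07 for legume families (74.4). With exact reference sequences only, the sign turned for auxin (0.03), other conserved families (-0.14), the small RNA pathway (0.14) and legume families (-0.12). With scaling to the median family it turned for phase change and flowering (-0.0055), developmental transcription factors (-0.02) and the phased siRNA triggers (-0.0020). For auxin it also turned with the most abundant sequence of each family only (0.09). The sign of the nutrient response list did not turn under the 6 alternatives run. Over all 34 families it was 0.06, at percentile 89.8. As background, the 10 control families not expected in chickpea reached at most 2 reads in the library labelled flower, 0.148 RPM, and 8 reads in the library labelled leaf, 0.317 RPM.

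**Figure D2:**
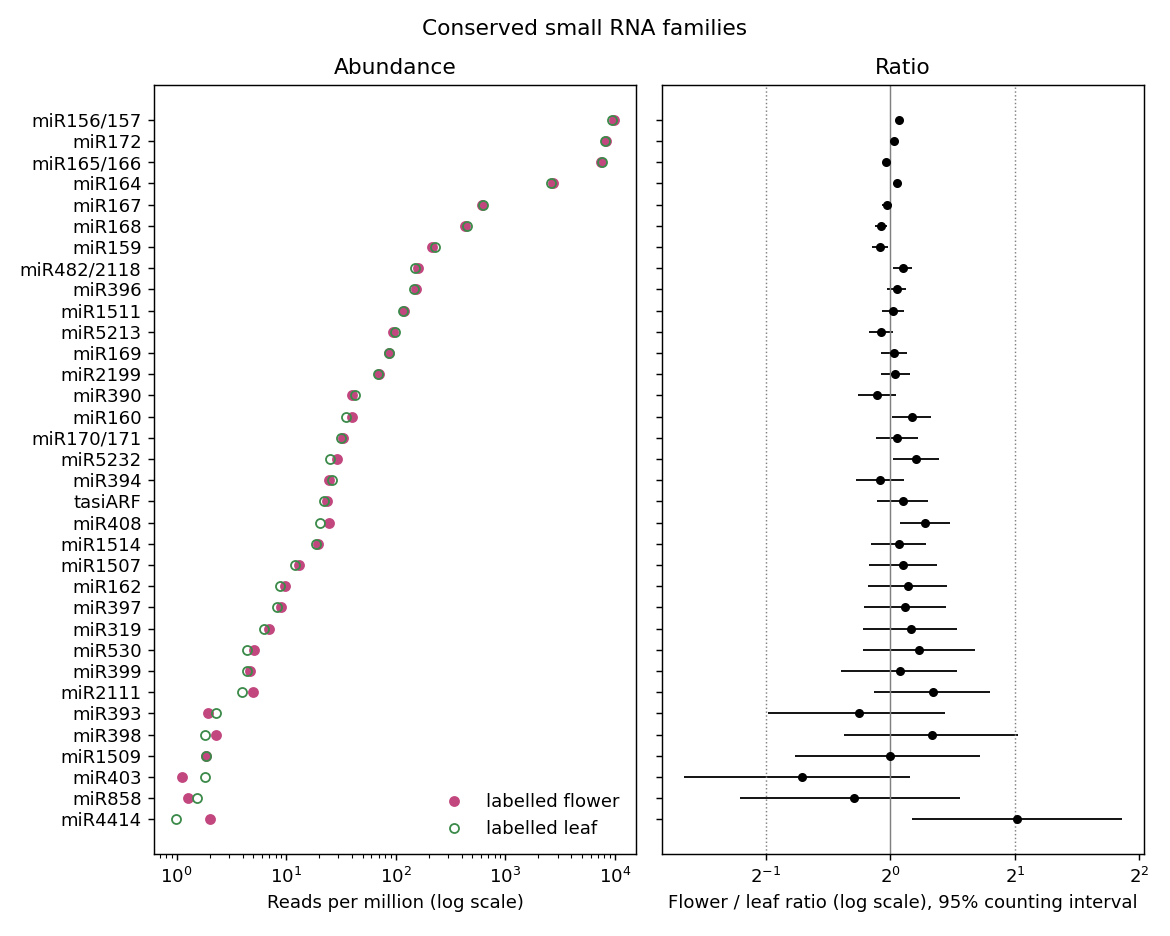
Left, RPM (log scale) of the 34 conserved families with at least 50 reads in the library labelled flower (filled) and the library labelled leaf (open); right, the ratio of flower-labelled to leaf-labelled values (log scale) with its 95% interval for counting error. Points cluster on the line of equal abundance, and miR4414, at 2.02, is the family past the dotted line for 2-fold.

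Tags of 20 to 22 nt outside the families were led by the same 5 sequences in both libraries. The first was GGCGAATGTAGCCAAGTGGA, the 5′ end of a chloroplast-type tRNA-His, with 5.62% of reads in the library labelled flower and 5.16% in the library labelled leaf, a ratio of 1.09 (1.09 to 1.09). Next came adapter tags of 21, 22 and 20 nt. The fifth was GTCGTTGTAGTATAGTGGTAA, the 5′ end of nuclear tRNA-Asp, with a ratio of 1.001 (0.995 to 1.01). Among tags with at least 500 reads, the 5 with the highest values in the library labelled flower relative to the other reached ratios of 1.34 to 1.64. GTCTCGGGAAAACGATCGTC had 234 and 267 reads, a ratio of 1.64 (1.37 to 1.96). ACTGAAGGTCCGTAGTTCGATC had 42348 and 57508 reads, a ratio of 1.38 (1.36 to 1.40), and 2 of the other tags, GCTGAAGGTCCGTAGTTCGATC and CCTGAAGGTCCGTAGTTCGATC, differed from it at the first base. AATCCGGGCTAGAAGCGATG had a ratio of 1.34 (1.15 to 1.56).

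In the other direction the differences were far larger. GGCTAATGGAGCCAAGTGGA had 0 and 980 reads and GGCCAATGGAGCCAAGTGGA 0 and 695 reads. GGCGGATGGAGCCAAGTGGA had 2 and 1330 reads, GGCGAATGGAGCCAAGTGGA 14 and 6382 reads, and GTTGTACAGTCCGACGATCGT 42 and 3571 reads. The latter 3 were single-substitution variants of tags at least 20 times more abundant. Counted from the 5′ end of the tag, with the abundant tag's base first, GGCGGATGGAGCCAAGTGGA and GGCGAATGGAGCCAAGTGGA carried T9G, and the adapter tag GTTGTACAGTCCGACGATCGT carried C4G.

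Such variants were counted over 1273 abundant tags at bases 1 to 18 and over fewer at later bases, which shorter tags lack, with 620 at base 23. At base 4 they made up 0.247% of the abundant tags' reads in the library labelled flower and 0.867% in the library labelled leaf. At base 9 the rates were 0.204% and 0.781%, and at base 23 they were 0.213% and 0.675%. At the other bases the leaf-labelled rate divided by the flower-labelled rate lay between 0.890 and 1.11. Of 3699 tags with at least 500 reads, 83 were at least 2-fold higher in the library labelled leaf and 0 in the library labelled flower. Of the 83, 27 held the adapter stretch defined above and were counted first as adapter tags, whether or not they also carried a variant. Some of them did, such as those with 19 and 4437 reads (base 4) and 500 and 6162 reads (base 9). Of the others, 49 were variants at base 4, 9 or 23 and 5 were variants at 2 of these bases. The last 2 had bases added at the 3′ end, with 0 and 791 and 0 and 625 reads. Both ended at base 23, and whether they were variants at that base was not tested. Random splits of the reads gave 0 tags at least 2-fold apart in either direction.

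**Figure D3:**
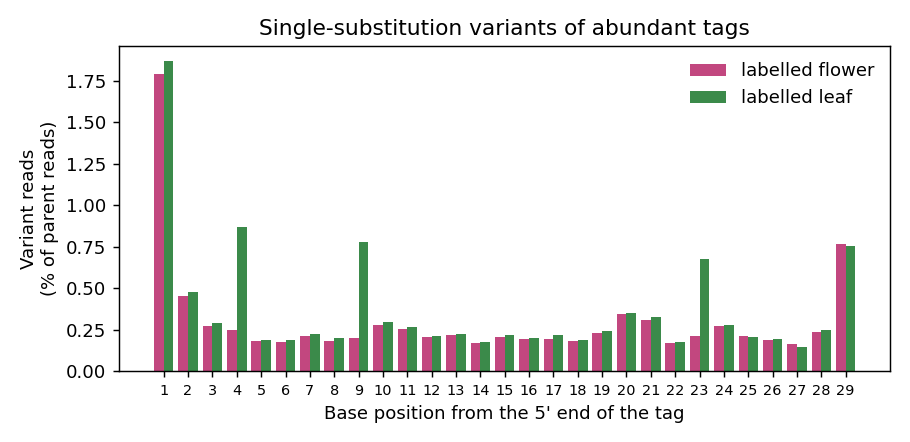
Reads of single-substitution variants of up to 1273 abundant tags per base (620 at base 23), in percent of the abundant tags' own reads, by base position from the 5′ end, in the library labelled flower and the library labelled leaf. The libraries part at bases 4, 9 and 23, where the library labelled leaf reaches 0.867%, 0.781% and 0.675%.

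The third comparison was the sharing of 24-nt siRNA sequences, after the library labelled leaf was thinned to the depth of the library labelled flower. Of 2285965 distinct 24-nt sequences in either library, 314114 were found in both, which is 13.7% (13.7 to 13.8, exact binomial interval). A random split of the same reads into 2 files of these depths would share 315331, and the observed number divided by it was 0.996. At the other lengths this value lay between 0.974 and 0.994, and over all lengths it was 0.9896. Of the 232253 sequences of 24 nt with 2 reads in all, 49.7% had 1 read in each library (49.5 to 49.9), against 49.99% in a random split. Over all lengths the share was 49.3% (49.2 to 49.5). Sharing as a percentage is limited by depth here, since most sequences were read once.

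Loci that give phased 21-nt siRNAs, and the genomic origin of the reads, need a genome sequence, which was not used here.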

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

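All tests in this part were chosen after the results were seen. The 5′ adapter is outside the small RNA measured, and its tags made up 17.97% of reads in the library labelled flower and 18.67% in the library labelled leaf, far above the limit that a count of 0 allows. Variants at bases 4, 9 and 23, which belong to no planned comparison, reached 0.867%, 0.781% and 0.675% of the reads of their abundant tags in the library labelled leaf.

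The first pattern is the near-equality of the libraries, from miR156/miR157 and miR172 to 24-nt siRNAs read once or a few times. A one-way spill of reads would leave tissue-specific tags if the receiving file kept a sizeable share of its own reads. Adapter tags, variants at 1 or 2 bases and tags with added bases were set aside. Of the tags with at least 500 reads, 0% were then 2-fold apart, which argues against such a spill. A near-total spill would leave no such tags either, so this test cannot decide on it. Reads of 1 library split with counting error alone are argued against by tags with at least 5000 reads, without adapter tags and variants. Their mean squared deviation was 85.8 times that of counting, with a spread beyond counting of 0.094 in log2 ratio. For tags of 20 to 49 reads, also without adapter tags and variants, it was 1.05 times. 1 pool of RNA behind both files, with differences between preparations or runs, may be the source, since shared 24-nt sequences divided by those of a random split gave 0.996; over all lengths it was 0.9896, and 25-nt sequences had the lowest value, 0.974. Alike small RNA populations in separately prepared libraries cannot be told apart from it, and equal mixing of both pools and a true likeness of the tissues stay open as untested, since no second library of either tissue gives a scale for the spread of log2 ratios beyond counting. Without adapter tags and variants that spread was 0.082 for tags with at least 1000 and under 5000 reads, the lowest of the abundance ranges, and 0.178 for those with at least 500 and under 1000, the highest; with them it was 0.318 in the former range.

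The second pattern is the tags found almost only in the library labelled leaf. RNA variants in leaf tissue are argued against at bases 4 and 9 by the adapter, which is synthetic and yet had variant rates at least 2.12 times higher in the library labelled leaf at these bases. At base 23 the adapter tags gave 1.14 times, which decides little, but 100% of 131 non-adapter tags with at least 5000 reads had the higher rate in the library labelled leaf. Miscalled bases in the run of the library labelled leaf need a rise in nearly all tags. At each of the 3 bases 97.2% or more of such tags had it, against 46.2% to 71.3% at the other bases. The 3 bases had been picked for their higher leaf-labelled rates over all abundant tags, which made high shares probable. The shares do show that the rise was not that of a few tags, so miscalling may be the source. Where the same nucleotides of non-adapter RNA lay at another position of the read, in tags with a shifted 5′ end, the leaf-labelled rate was 1.04 times the flower-labelled one, against 4.65 times at the 3 bases; the rates by base seen before had made a value near 1 probable.

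The third pattern is that long adapter tags were rarer in the library labelled flower, with ratios of 0.976 at 22 nt, 0.496 at 23 nt, 0.0880 at 24 nt and 0.0196 at 25 nt. The fall was not steady, since the 26-nt tag had 8 and 45 reads, few in either library, and a ratio of 0.333, and the 27-nt tag had 8 and 4096 reads and a ratio of 0.0037. A loss of all reads of that length is argued against by the other 25-nt reads, with a ratio of 0.963. Adapter reads removed or trimmed differently in the files before deposit could give the 0.0196, but no step is given in the sources used here, so this stays open. No biological explanation was tested, since the adapter is synthetic.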

How the results depend on the processing

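Alternatives without adapter, tRNA and rRNA, and without the variants at bases 4, 9 and 23, were chosen after seeing the data; the others were planned. The number of families at least 2-fold higher in the library labelled flower was 1, and was 0 with scaling to the median family, exact reference sequences only, the most abundant sequence of each family only, tags with at least 5 reads, at least 500 reads per family, or equal depth. It was 2 with no minimum number of reads, where the number in the library labelled leaf was 1 in place of 0. The family counted as higher in the library labelled flower in the main setting was miR4414, with 52 reads. Exact sequences left it 0 reads, its most abundant sequence 38, tags with at least 5 reads 46 and equal depth 42, all under the minimum of 50. At equal depth its 27 and 15 reads were also less than 2-fold apart. Its ratio was 2.31 with its most abundant sequence, 2.66 with tags of at least 5 reads and 1.95 with scaling to the median family. The median log2 ratio of all families was 0.06, and moved to 0.00037 with scaling to the median family, by construction, and to 0.094 with exact reference sequences. In the latter setting families with fewer than 50 exact reads left the median, so it is over fewer families than the 34. How far this gave the move was not tested. The ratio of 24-nt to 21-nt reads, 1.33 and 1.37, became 7.01 and 7.07 over distinct sequences. It was 1.85 and 1.90 without the 10 most abundant tags, and 2.003 and 2.048 without adapter, tRNA and rRNA. With tags of 2 or more reads it was 0.850 and 0.952. That setting keeps more of the deeper library. It also kept adapter, tRNA and rRNA, which weigh more on the 21-nt class. The library labelled leaf had the higher value in each setting. The share of 24-nt sequences in both libraries was 13.7%, 13.9% at the deposited depth and 29.99% among sequences with 2 or more reads in a library, since sequences read once drop out. Of 147 ratios of named families over 6 alternatives, computed without the minimum of 50 reads, 131 stayed within the counting interval. These ratios ran from 0.562 to 2.66, 4 were at or above 2-fold and 0 at or below 1 in 2. Of 48 list medians, 40 stayed within their interval, each over the families that kept at least 50 reads in the setting. Alternatives that need genome matches, annotation classes and phased loci were not run. No paired analysis was possible because there is 1 library per tissue.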

Other observations

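The tests in this part, like the classes of tRNA and rRNA, were chosen after the data were seen. Many fragments of tRNA and rRNA began at the first base of the listed sequence; the shares are over the reads of both libraries together. These sequences were written from general knowledge after the tags were seen and were not checked against a database, so their first bases are not independent of the tags. Of reads that matched the start of 18S rRNA, 94.5% began at its first base, and the most abundant, TACCTGGTTGATCCTGCCAGTAG, had 528591 reads in the library labelled flower and 963358 in the library labelled leaf. Of reads matching 5.8S rRNA, 80.5% began at the first base. Reads of chloroplast-type tRNA-Arg-ACG began at its first base in 99.9% of cases, those of tRNA-Gly-GCC in 99.9%, and those of nuclear tRNA-Asp-GUC in 98.7%. The share was lower for tRNA-His-GUG form 1, at 74.99%, and tRNA-Pro-UGG, at 59.3%, and it was 0.0828% for 5S rRNA. Chloroplast-type tRNA-Arg-ACG and both forms of tRNA-His-GUG had ratios of 1.12, 1.10 and 1.14, while tRNA-Gly-GCC had 0.954.

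Several microRNA families were read mostly at a length other than 21 nt. miR482/miR2118, miR1507 and miR1514, at 93.6%, 97.3% and 70.1% of reads, were mainly 22 nt long, the length linked to phased siRNA production in plants, as were miR167 at 65.7% and miR393 at 75%. In miR5213 the 22-nt reads made up 27.3%. miR1511, a legume family, stood at 118.1 and 116.6 RPM, and miR164, which targets NAC transcription factors, at 2732 and 2630.

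Adapter tags, tags with added bases, variants at 1 base of tags 20 times more abundant, and variants at 2 of bases 4, 9 and 23 were set aside. Of the other tags with at least 50 reads and at least 2-fold apart, 3 had no read in 1 library. They are named here after their values were seen. GGCGCATGTAGCCAAGTGGATCAAG had 150 reads in the library labelled flower and GGCGCATGTAGCCAAGTGGATCACG 71 reads, with 0 of either in the library labelled leaf. The former carries A5C, counted from the 5′ end, relative to its most abundant single-base neighbour. The 20-nt fragments with C at this position did occur in both libraries, with 358 and 49 reads. Among the 25-nt tRNA-His fragments, the forms with A there had 651 and 1188 reads and those with G 329 and 496 reads. GTCGTTGTAGTATAGTGGTAAGGATTC ran the other way, with 0 and 337 reads. It carries T23G relative to GTCGTTGTAGTATAGTGGTAAGTATTC, which had 1675 and 3269 reads.

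Of 31004 tags with at least 50 reads, 64 were at least 2-fold higher in the library labelled flower, against a mean of 45.0 and a highest value of 59 in 20 random splits. In the library labelled leaf the number was 677, against a mean of 123.7 and a highest value of 142. Of the 677, 115 were neither adapter tags, variants nor tags with added bases.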
